A study of Homo sapiens with 21 samples.

How the data were processed

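Needle biopsies of vastus lateralis, the large muscle on the outer side of the thigh, were compared in 7 participants at 3 times, which made 21 arrays. The times were baseline, the end of 48 h of unilateral lower limb suspension (unloading), and 24 h after weight bearing was resumed (reloading). Per the labels' protocols, total RNA was extracted with Trizol and purified on RNeasy columns, and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays of 54675 probe sets. A probe set is a group of short probes for 1 transcript. The labels do not state that the leg biopsied was the suspended one, and this is assumed here.

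The deposited values are array intensities on a linear scale, 1 per probe set and array, made with MAS5 according to the submitters' processing notes. The MAS5 version, its settings and any detection calls are not given in the sources used here, nor are scan dates or other batch labels. The values show that each array had been scaled as a whole: the mean intensity after trimming 2% of the values at each end was 800.1 on every array, to 1 decimal, while the array medians ran from 204.5 to 277.3. The log2 medians spanned 0.44, under the limit of 0.5 set for a further normalization, so none was applied. Values below 1, which were 37 of 1148175, were set to 1 before the log2 was taken, and the lowest deposited intensity was 0.482. MAS5 scaling with 1 factor per array leaves differences in the shape of the intensity distribution in place, so changes are relative to each array's trimmed mean. Arrays carry no read depth, and their number limits the precision.

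The 62 control probe sets were left out of all gene tests. Of the others, 41091 had exactly 1 gene symbol in the platform annotation used, 1801 had several and 11721 had none, and those with several or none were not named or tested. Symbols of 41037 probe sets were matched through their gene identifiers with 0 updates, and 54 were kept as the annotation gave them. Each of the 19775 genes was represented by its brightest probe set over all arrays. A gene was tested where that mean reached the median of all probe sets, a log2 intensity of 7.66, which left 12258 genes. Genomic coordinates are not given in the sources used here and are not printed.

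Differences were tested on the log2 scale with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend, two-sided. The 21 arrays entered 1 fit with the participant as a fixed block and the time as group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12258 genes of that comparison. Errors given as SE are limma's standard errors unless an SD is named, and n is 7 participants throughout unless stated. In the text "rose" and "fell" are used for what passed its test, and other values are given as measured.

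The series text says that the same participants gave a biopsy at each time, and the replicate numbers come from the sample titles. As a check of the pairing, each array's deviations from its group mean were correlated across genes with those of the other groups' arrays. Same-numbered arrays had correlations from 0.0459 to 0.408 with a median of 0.246, and 18 of 21 such pairs were above 0.1. Arrays of different numbers had a median correlation of -0.0354, and each of the 21 arrays correlated best with an array of its own number. The first principal component held 13.5% of the variance, of which 86.8% lay between participants and 6.53% between groups.

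Gene groups were 34 lists of genes and 11 lists of cell type markers, all fixed, like the tests, the rule for named genes and the first set of alternatives, before the data were examined. Of these 45 lists, 44 had at least 5 members among the genes tested. They were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 132 tests (44 lists in 3 comparisons). Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. A list's size is given as the mean log2 change of its members with the SE over the 7 participants' own means. Member counts are given over all genes tested and adjusted over the list alone.

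Genes named in the text were chosen by rule in each comparison: the 12 largest rises and 12 largest falls among called genes that moved the same way in at least 6 of 7 participants, all that passed where fewer than 10 did, the 4 members with the smallest p of each list called, and 2 of each list not called. Left out were genes named only by clones or open reading frames and genes whose levels can mark 1 person. Where a gene outside this rule is named, the text says so.

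Alternatives, whose effects are in the closing section, were no participant block, the block as a random effect, only the 14 arrays compared, quantile normalization, median centring, other filters on dim probe sets, log2 of the value plus 32, eBayes without a trend or robust, array weights, the mean of a gene's probe sets, only probe sets without the suffixes _s_at and _x_at (which can match several transcripts), a fold of at least 1.5 as well, and leaving out each participant in turn. Leaving out 1 baseline array (replicate 5) and 1 unloading array (replicate 4) was added after the data had been seen. The fit was tested on simulated data: in 10 simulations of unloading against baseline with 12258 genes, it recovered 44.2% of changes of 0.5 log2, 78.4% of changes of 1 and 97.8% of changes of 2, and 4.50% of its calls were false. For reloading against baseline the recovered shares were 40.4%, 78.6% and 97.8% with 3.66% false calls, and for reloading against unloading 38.2%, 76.0% and 98.4% with 5.48% false calls. The simulated noise was drawn independently for each gene from the fitted spread. Genes on real arrays vary together, so the shares of false calls do not show how the fit performs there. Array measures, which were the median, the interquartile range, the 3' to 5' ratio of control probe sets for GAPDH and ACTB, and marker means, were compared within participants with an exact permutation test. Permutations were enumerated in R. The values were prepared and the figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.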

Results

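Thigh muscle was sampled from 7 participants before, at the end of and after a short period in which 1 leg did not bear weight. In unilateral lower limb suspension the leg is held off the ground and the participant walks on crutches, so that muscles of the suspended leg stay innervated but carry no load. Vastus lateralis biopsies at baseline, after 48 h of this unloading and after 24 h of reloading gave 7 arrays per time, 21 in all, and 12258 genes were bright enough to test. The same thigh was biopsied at every time, and no repeat biopsies without suspension were analysed here, so every difference between times also holds the effect of time and of the earlier biopsies. Among 30 exact permutation tests of array medians, spread, 3' to 5' ratios and marker means the smallest p was 0.0625 and the smallest adjusted p 0.508. With 7 pairs p cannot be below 0.0156, so a single measure that moved in every participant would not pass over 30 tests either, and the tests do not show that array quality stayed the same.

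The first comparison asks what 48 h without load does to muscle transcripts. HMOX1, which encodes the inducible heme oxygenase that frees iron from heme, rose 12.4-fold over baseline, by 3.64 ± 0.57 log2 (SE, n = 7, adjusted p = 0.0102), and was higher in 7 of 7 participants. Its baseline mean, a log2 intensity of 8.11, was close to the mean array median of 7.94, and without detection calls it is not shown to be above background. The fold is therefore against a dim signal. TFRC, the transferrin receptor that brings iron into cells, fell 2.86-fold, by -1.52 ± 0.24 log2 (adjusted p = 0.0102), and was lower in 7 of 7. EGR1, an immediate early transcription factor, rose 4.08-fold. As lists, transcripts of heat shock proteins fell by -0.18 ± 0.05 log2 on average over 33 genes (24 lower, 9 higher), and metallothioneins, small metal-binding proteins, rose by 0.44 ± 0.16 log2 over 10 genes (8 higher, 2 lower). Neither list was called with an estimated correlation between genes (adjusted p = 0.315 and 0.394). In all, 21 genes were called, of which 14 rose and 7 fell.

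HMOX1 had a mean log2 intensity of 8.11 ± 1.03 (SD, n = 7) at baseline and 11.75 ± 1.61 after unloading, and the 95% interval of its change ran from 2.45 to 4.83 log2. TFRC had means of 14.06 ± 0.66 and 12.55 ± 0.62. EGR1 rose by 2.03 ± 0.35 log2 (adjusted p = 0.0197). ARG2, a mitochondrial arginase, rose by 1.07 ± 0.21 log2 (adjusted p = 0.0396) in 6 of 7 participants, but its other probe set gave 0.17. OIP5, a protein of centromere assembly, rose by 0.91 ± 0.18 log2 and TSPAN8, a tetraspanin of the cell surface, by 0.89 ± 0.15. COL4A3, a chain of basement membrane collagen, rose by 0.78 ± 0.12 log2 (adjusted p = 0.0102) and UNKL, a zinc finger protein, by 0.75 ± 0.11 (adjusted p = 0.0102).

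Smaller rises, all in 7 of 7 participants, were those of ATOSA (0.73 ± 0.14 log2), the arrestin-domain gene ARRDC2 (0.73 ± 0.13), the chemokine CXCL14 (0.66 ± 0.12), RC3H1 (0.52 ± 0.10), which encodes the mRNA decay factor roquin, and the centrosomal CEP85L (0.52 ± 0.10), with adjusted p from 0.0309 to 0.0389. SSH2, a phosphatase that activates cofilin, rose by 0.51 ± 0.08 (adjusted p = 0.0102) and ITPRID2 by 0.47 ± 0.09 (adjusted p = 0.0344). These 2 lie outside the rule of 12 rises and were named after their values were seen. The other probe sets of ITPRID2 gave -0.22 and -0.35, with mean log2 intensities of 8.67 and 6.17, the latter below the filter's 7.66.

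Among the falls, DNAJA4 (-0.89 ± 0.16 log2, adjusted p = 0.0197) and DNAJB4 (-0.59 ± 0.10, adjusted p = 0.0197) encode co-chaperones of HSP70. DYNLL1, a light chain of cytoplasmic dynein, fell by -0.67 ± 0.11 log2 (adjusted p = 0.0102). TP53INP2, a regulator of autophagy, fell by -0.69 ± 0.13 log2 (adjusted p = 0.0344) and TIMM8A, a chaperone of mitochondrial protein import, by -0.65 ± 0.12 (adjusted p = 0.0326). STYXL1, a phosphatase-like protein, fell by -0.82 ± 0.15 log2 (adjusted p = 0.0309), while its other 4 probe sets gave values from -0.44 to 0.06. These genes were lower in 7 of 7 participants. Other probe sets of genes named above disagreed in size or sign too: EGR1 at 0.76 and 1.59, UNKL at 0.15 and 0.31, RC3H1 at 0.06 and 0.39, COL4A3 from -0.03 to 0.99, SSH2 from -0.12 to 0.91 and CEP85L at 0.22. CXCL14 stood at -0.19 and 0.75, DNAJA4 from -0.80 to -0.15 and TFRC from -1.74 to -0.41. Some of these probe sets were dim, with a mean log2 intensity below the filter's 7.66. They gave the -0.19 of CXCL14, the -0.03 of COL4A3, the -0.12 of SSH2 and the -0.41 of TFRC. The 0.15 of UNKL, the 0.22 of CEP85L and the 0.06 of STYXL1 came from dim probe sets too. The 0.06 of RC3H1 came from a brighter one, at 9.76.

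**Figure D1:**
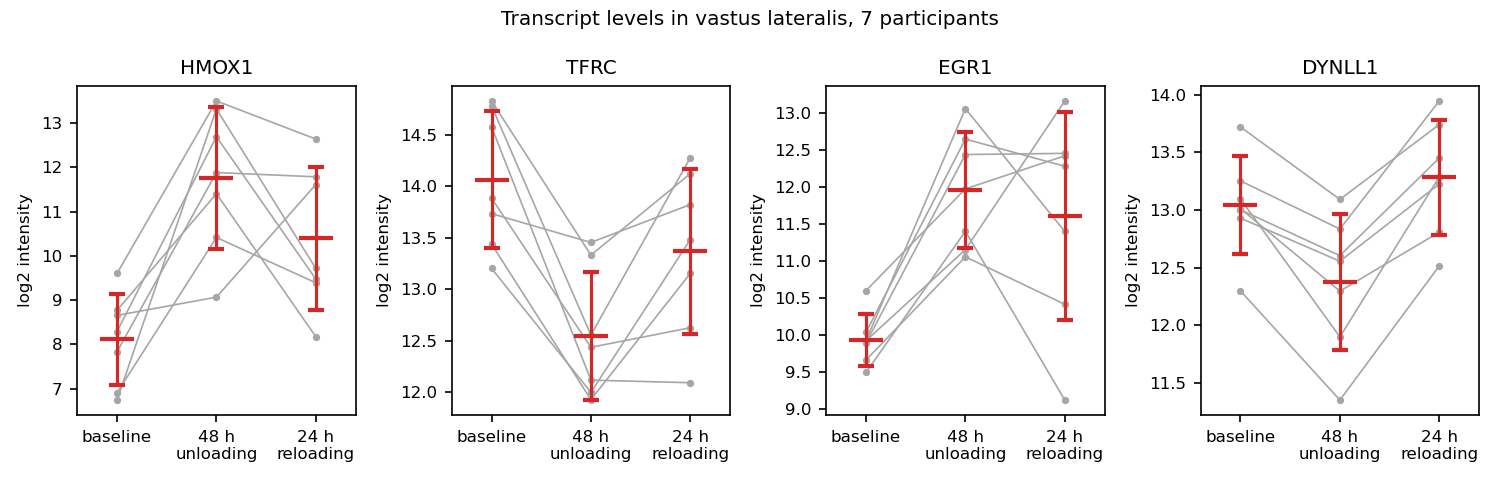
Log2 intensity of HMOX1, TFRC, EGR1 and DYNLL1 (vertical axis) at baseline, after 48 h of unloading and after 24 h of reloading; grey lines join the 3 arrays of each of the 7 participants, and red marks give the mean ± SD. HMOX1 and EGR1 were higher and TFRC and DYNLL1 lower after unloading in every participant, and the DYNLL1 mean after reloading, 13.28, was above its unloading mean of 12.38.

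The number of calls depends on the pairing and on single participants: without the participant block 0 of the 12258 genes were called (587 at an unadjusted p under 0.05, limma), against 21 with it (1148 at an unadjusted p under 0.05). Leaving out participant 7 left 1 gene (TFRC), participant 1 left 6, participant 5 left 8 and participant 4 left 9, while leaving out the unloading array of replicate 4 left 11 and the baseline array of replicate 5 left 10. Scaling moved the balance of directions, from 14 rises and 7 falls to 23 and 4 with median centring and to 9 and 7 with quantile normalization. HMOX1 passed at 18 of 22 alternative settings, and its adjusted p was 0.0604 without participant 7.

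Of the 44 gene lists, 11 were called after unloading, 5 higher and 6 lower than baseline. With an estimated correlation 0 of the 44 were called, and fry called 1, the heat shock list (adjusted p = 0.0462). At least 11 lists were also called in 22 of 100 splits of the same 14 arrays, the real one included, so the number of lists does not stand apart from other groupings of these arrays.

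Heat shock proteins and chaperones, which help other proteins fold, fell in 7 of 7 participants (adjusted p = 5.95e-06, and adjusted p = 0.315 with an estimated correlation). Of 33 members, 1 fell over all genes tested (DNAJB4), 32 did not pass, and 7 fell adjusted over the list alone. HSPH1 (-0.49 ± 0.11 log2, adjusted p = 0.0925), HSP90AA1 (-0.36 ± 0.08, adjusted p = 0.0925) and HSPA4L (-1.12 ± 0.28, adjusted p = 0.129) had the next smallest p. In all, 24 members were lower and 9 higher. Listed but not tested, as no probe set had exactly 1 symbol, were the HSP70 genes HSPA1A, HSPA1B and HSPA8, and AHSA1 and HSF2.

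Metallothioneins and zinc transporters rose (adjusted p = 3.16e-05, and adjusted p = 0.394 with an estimated correlation) in 6 of 7 participants. None of the 10 members passed over all genes, 7 rose adjusted over the list alone, and MT1E (0.90 ± 0.25 log2), MT2A (0.73 ± 0.20), MT1G (0.72 ± 0.18) and MT1X (0.53 ± 0.14) had adjusted p from 0.128 to 0.205 over all genes. Their sequences are close to each other, so a probe set can read more than 1 of them. Targets of the glucocorticoid receptor and FOXO factors, which hold MT2A as well, rose by 0.24 ± 0.11 log2 on average (adjusted p = 1.04e-05, and adjusted p = 0.315 with an estimated correlation), with 19 of 21 members higher, 0 passing over all genes and 1 adjusted over the list alone. KLF9, a hormone-induced transcription factor, stood at 0.30 ± 0.11 log2 (adjusted p = 0.377) and CEBPB at 0.20. Genes of the oxidative stress response rose by 0.22 ± 0.06 log2 on average with a median of 0.06 (adjusted p = 0.0075, and adjusted p = 0.315 with an estimated correlation) in 7 of 7 participants. Of 28 members only HMOX1 passed, over all genes and adjusted over the list alone. Its change of 3.64 log2 is a large single share of the list's mean, and the mean without HMOX1 was not computed. GPX3 stood at 0.46 ± 0.15 and GCLM at 0.31 ± 0.16, and without participant 7 the list's adjusted p was 0.0536.

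Genes of growth factor, AKT and mTOR signalling rose by 0.10 ± 0.05 log2 (adjusted p = 0.0184, and adjusted p = 0.323 with an estimated correlation) in 5 of 7 participants. None of 31 members passed over all genes, and adjusted over the list alone 1 rose and 1 fell: DEPTOR, an inhibitor of mTOR (0.31 ± 0.08 log2), and, against the list, IGFBP6, which binds insulin-like growth factor (-0.53 ± 0.14). INSR, the insulin receptor, stood at 0.32 ± 0.12 log2. The call was lost without participant 7 (adjusted p = 0.115), without the unloading array of replicate 4 (0.0677), with a filter at the 75th percentile (0.0656), with the mean of probe sets (0.207) and with fry.

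Genes of the extracellular matrix rose by 0.11 ± 0.07 log2 (adjusted p = 0.0322, and adjusted p = 0.708 with an estimated correlation) in 5 of 7 participants, with 0 of 54 members passing over all genes and 1 adjusted over the list alone. CTHRC1, secreted by fibroblasts that lay down matrix, stood at 0.81 ± 0.19 log2 (adjusted p = 0.0925), PCOLCE at 0.85 ± 0.29 and COL5A2 at 0.49 ± 0.17, and against the list the protease MMP9 stood at -0.63 ± 0.18. Markers of fibroblasts, which share genes with the matrix list, had a mean change of 0.16 ± 0.09 log2 (adjusted p = 0.0604). Those of adipocytes had 0.24 ± 0.33 (adjusted p = 0.0893). The adipocyte mean on the unloading array of replicate 4 was 13.04, against 10.82 on the next of the 7. Without that array the matrix list had adjusted p = 0.214, and without participants 3, 4 or 6 or the baseline array of replicate 5 it had 0.0652, 0.155, 0.317 and 0.116. It also missed the threshold without the participant block (0.0798), with the block as a random effect (0.0596), median centring (0.0716), a filter at the 75th percentile (0.171), array weights (0.131), the mean of probe sets (0.1001) and fry. The call was lost in 13 of 24 settings.

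Transcripts of mitochondria and of slow fibres were lower after unloading by small amounts. Oxidative phosphorylation fell by -0.06 ± 0.05 log2 (adjusted p = 0.00123, and adjusted p = 0.711 with an estimated correlation) with 62 of 70 members lower, but 4 of 7 participants had a higher mean, and the mean was 0.01 with median centring. None of its members passed over all genes or adjusted over the list alone, and NDUFS4, a subunit of complex I, stood at -0.24 ± 0.09. The TCA cycle list fell by -0.05 ± 0.03 (adjusted p = 0.0266, and adjusted p = 0.66 with an estimated correlation) in 7 of 7 participants, with a mean of 0.01 under median centring, 0 members passing either way, and the pyruvate carrier MPC1 at -0.22 ± 0.08. Mitochondrial biogenesis and dynamics fell by -0.09 ± 0.04 (adjusted p = 0.00764, and adjusted p = 0.459 with an estimated correlation), with 0 of 25 members passing either way and the outer membrane channel VDAC2 at -0.19 ± 0.06. The mitochondrial ribosome fell by -0.08 ± 0.04 (adjusted p = 0.00127, and adjusted p = 0.459 with an estimated correlation), with 0 of 38 members passing over all genes and 1 higher and 3 lower adjusted over the list alone. MRPS12 stood at -0.34 ± 0.08, and MRPS16, against the list, at 0.30 ± 0.09, or -0.12 without probe sets ending in _s_at or _x_at.

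Slow fibre genes of the sarcomere and of calcium handling fell by -0.17 ± 0.12 log2 (adjusted p = 0.002, and adjusted p = 0.641 with an estimated correlation), with all 15 members lower, 4 of 7 participants lower, 0 members passing over all genes and 2 adjusted over the list alone. CASQ2, a calcium store protein, stood at -0.60 ± 0.16 log2 (adjusted p = 0.165) and PLN, the inhibitor of the calcium pump, at -0.31 ± 0.09. The slow fibre call was lost without participants 4, 5 or 6 (adjusted p = 0.0849, 0.0728 and 0.104) or the baseline array of replicate 5 (0.0727). Oxidative phosphorylation lost its call without participant 4 or 5 (adjusted p = 0.0700 and 0.325), that baseline array (0.159) or the unloading array of replicate 4 (0.0826). The TCA list did without participant 4 or 5 (0.338 and 0.0897) or those arrays (0.0935 and 0.338), without the participant block (0.132) and with it as a random effect (0.0860). Mitochondrial biogenesis did without participant 4 (0.0673) or that participant's unloading array (0.0505) and with the mean of probe sets (0.0680). With median centring the 4 mitochondrial lists had adjusted p from 0.0570 to 0.210, and the means of biogenesis and of the mitochondrial ribosome were -0.02 each. Heat shock and slow fibre genes were still called, with means of -0.11 and -0.10.

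The comparison of reloading with baseline asks what 24 h of weight bearing leaves of the difference. As lists, transcripts of mitochondrial energy metabolism fell: oxidative phosphorylation by -0.18 ± 0.06 log2 on average, or -12.0%, with 70 of 70 members lower and 7 of 7 participants lower, and the TCA cycle by -0.22 ± 0.05 log2, or -14.1%, in 7 of 7. With an estimated correlation neither was called (adjusted p = 0.387 and 0.315), and 0 members of either passed over all genes. Equally bright genes were lower as well: 95% of random lists matched to oxidative phosphorylation on expression had means between -0.112 and -0.0454. Immediate early genes, inflammatory genes, metallothioneins and genes of ribosome biogenesis rose as lists, but not with an estimated correlation (adjusted p = 0.459, 0.394, 0.459 and 0.459), and 0 of their members passed over all genes. Single genes were few: TMEM140 rose 2.14-fold (1.10 ± 0.18 log2, adjusted p = 0.0451), SSH2 rose by 0.45 ± 0.08 (adjusted p = 0.0494) and TP53INP2 fell by -0.85 ± 0.13 (adjusted p = 0.0451), each in 7 of 7 participants. The other 4 probe sets of SSH2 gave values from 0.05 to 0.87, and only the one at 0.87 had a mean log2 intensity above the filter's 7.66.

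At an adjusted p under 0.10, 53 genes passed, and 1503 did at an unadjusted p under 0.05 (612.9 by chance). Without the participant block 0 genes were called (764 at an unadjusted p under 0.05, limma). The count moved with single participants: 19 genes without participant 3, 1 without participant 4, 0 without participant 1, 2, 6 or 7 (1476, 1254, 1131 and 1385 at an unadjusted p under 0.05), 0 without the baseline array of replicate 5 (1386) and 28 without the unloading array of replicate 4. The 2 rises and 1 fall became 3 and 3 with quantile normalization. HMOX1, the heme oxygenase, stood at 2.28 ± 0.57 log2 over baseline (adjusted p = 0.109) and TFRC at -0.70 ± 0.24 (adjusted p = 0.227), TFRC being named after its value was seen.

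Of the 44 lists, 13 were called, 5 higher and 8 lower, against 0 with an estimated correlation and 2 with fry, which were the TCA cycle and the mitochondrial ribosome (adjusted p = 0.0462 each). Other splits of the same 14 arrays gave at least 13 lists in 23 of 100, the real one included.

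Among the 70 oxidative phosphorylation genes (adjusted p = 3.22e-23, and adjusted p = 0.387 with an estimated correlation), 0 passed over all genes tested, 26 fell adjusted over the list alone and 43 were lower at an unadjusted p under 0.05. The complex I subunits NDUFA8 (-0.38 ± 0.08 log2) and NDUFS6 (-0.35 ± 0.07) had adjusted p = 0.0625, and the ATP synthase subunit ATP5PO stood at -0.27 ± 0.07 (adjusted p = 0.110). The TCA list (adjusted p = 1.51e-10, and adjusted p = 0.315 with an estimated correlation) had 0 of 22 members passing over all genes and 11 falling adjusted over the list alone, with MDH1, malate dehydrogenase, at -0.38 ± 0.09 and MPC1 at -0.31 ± 0.08. The mitochondrial ribosome fell by -0.15 ± 0.04 log2 (adjusted p = 1.67e-08, and adjusted p = 0.315 with an estimated correlation) in 6 of 7 participants, with 0 of 38 members passing over all genes and 9 adjusted over the list alone. Its members MRPS12 (-0.39 ± 0.08) and MRPL16 (-0.34 ± 0.07) had adjusted p = 0.0675. Mitochondrial biogenesis and dynamics fell by -0.12 ± 0.02 (adjusted p = 3.02e-04, and adjusted p = 0.315 with an estimated correlation), with 0 of 25 members passing over all genes and 6 adjusted over the list alone. PPARGC1A, the coactivator that drives mitochondrial gene expression, stood at -0.50 ± 0.14 (adjusted p = 0.139) and the ADP/ATP carrier SLC25A4 at -0.33 ± 0.08 (adjusted p = 0.109).

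Fatty acid oxidation and transport fell by -0.14 ± 0.04 log2 (adjusted p = 2.37e-05, and adjusted p = 0.315 with an estimated correlation) in 7 of 7 participants, with 0 of 26 members passing over all genes and 8 falling and 2 rising adjusted over the list alone. CD36, a fatty acid transporter, stood at -0.53 ± 0.14 log2, LPL, lipoprotein lipase, at -0.49 ± 0.15 and ETFB, an electron carrier of beta oxidation, at -0.35 ± 0.09. Glycolysis and glycogen metabolism fell by -0.06 ± 0.06 (adjusted p = 0.00504, and adjusted p = 0.593 with an estimated correlation), although 4 of 7 participants had a higher mean. None of its 27 members passed over all genes, and adjusted over the list alone 3 fell and 1 rose. The glycogen enzymes UGP2 (-0.30 ± 0.07) and GYS1 (-0.40 ± 0.12) were lower, while PFKFB3, which makes the activator of glycolysis, stood at 1.27 ± 0.32 (adjusted p = 0.109), against the list. The glycolysis call was lost without participant 5 or 6 (adjusted p = 0.0728 and 0.158), without the baseline array of replicate 5 (0.0756), with quantile normalization (0.271), without probe sets ending in _s_at or _x_at (0.242) and with fry.

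Slow fibre genes fell by -0.23 ± 0.13 log2 (adjusted p = 2.51e-05, and adjusted p = 0.459 with an estimated correlation) in 6 of 7 participants, with 15 of 15 members lower, 0 passing over all genes and 2 adjusted over the list alone. CASQ2 stood at -0.72 ± 0.16 log2 (adjusted p = 0.0698) and PLN at -0.29 ± 0.09. Genes of mechanosensing and of the costamere, which ties the sarcomere to the membrane, fell by -0.08 ± 0.06 (adjusted p = 0.0109, and adjusted p = 0.51 with an estimated correlation) in 4 of 7 participants, with 0 of 41 members passing over all genes and 4 adjusted over the list alone. The M-band protein MYOM2 stood at -0.39 ± 0.09 and ITGB1BP2, melusin, at -0.51 ± 0.12. The mechanosensing call was lost in 7 of 24 settings. These were without participant 3 or 6 (adjusted p = 0.132 and 0.157), with quantile normalization (0.338), the mean of probe sets (0.0949), an estimated correlation and fry, and without probe sets ending in _s_at or _x_at (0.0926). Markers of muscle fibres had a mean change of -0.06 ± 0.11 log2 (adjusted p = 0.0587) and those of fibroblasts -0.18 ± 0.13 (adjusted p = 0.0503).

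Immediate early genes rose by 0.34 ± 0.18 log2 (adjusted p = 0.0116, and adjusted p = 0.459 with an estimated correlation) in 6 of 7 participants, with 0 of 21 members passing over all genes and 3 adjusted over the list alone. FOS stood at 1.73 ± 0.46 log2 (adjusted p = 0.132), JUNB at 1.69 ± 0.54 (adjusted p = 0.187) and EGR1 at 1.67 ± 0.35 (adjusted p = 0.0625). Inflammation and chemokines rose by 0.17 ± 0.12 (adjusted p = 0.00908, and adjusted p = 0.394 with an estimated correlation) in 4 of 7, with 0 of 21 members passing over all genes and 2 adjusted over the list alone: STAT3, the cytokine-activated transcription factor (0.41 ± 0.10), and OSMR, the oncostatin M receptor (0.87 ± 0.23). Without participant 6 these lists had adjusted p = 0.218 and 0.0565, and without participant 2 the immediate early list had 0.0536. With a filter at the 75th percentile they had 0.225 and 0.153.

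Metallothioneins rose by 0.38 ± 0.19 log2 (adjusted p = 8.84e-04, and adjusted p = 0.459 with an estimated correlation), with 0 of 10 members passing over all genes and 3 adjusted over the list alone, MT1G at 0.66 ± 0.18 and MT2A at 0.65 ± 0.20. Glucocorticoid and FOXO targets rose by 0.20 ± 0.08 (adjusted p = 0.0024, and adjusted p = 0.459 with an estimated correlation), with 0 of 21 members passing over all genes and 3 adjusted over the list alone. TRIM63 (0.49 ± 0.14) and FBXO32 (0.42 ± 0.12), the ubiquitin ligases MuRF1 and atrogin-1 of muscle atrophy, had adjusted p = 0.146. The glucocorticoid and FOXO call was lost without probe sets ending in _s_at or _x_at (adjusted p = 0.278). Ribosome biogenesis and translation initiation rose by 0.14 ± 0.08 (adjusted p = 3.83e-04, and adjusted p = 0.459 with an estimated correlation) in 5 of 7 participants, with 0 of 35 members passing over all genes or adjusted over the list alone, the rRNA processing factors DDX21 and UTP4 standing at 0.40 ± 0.15 and 0.37 ± 0.11.

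**Figure D2:**
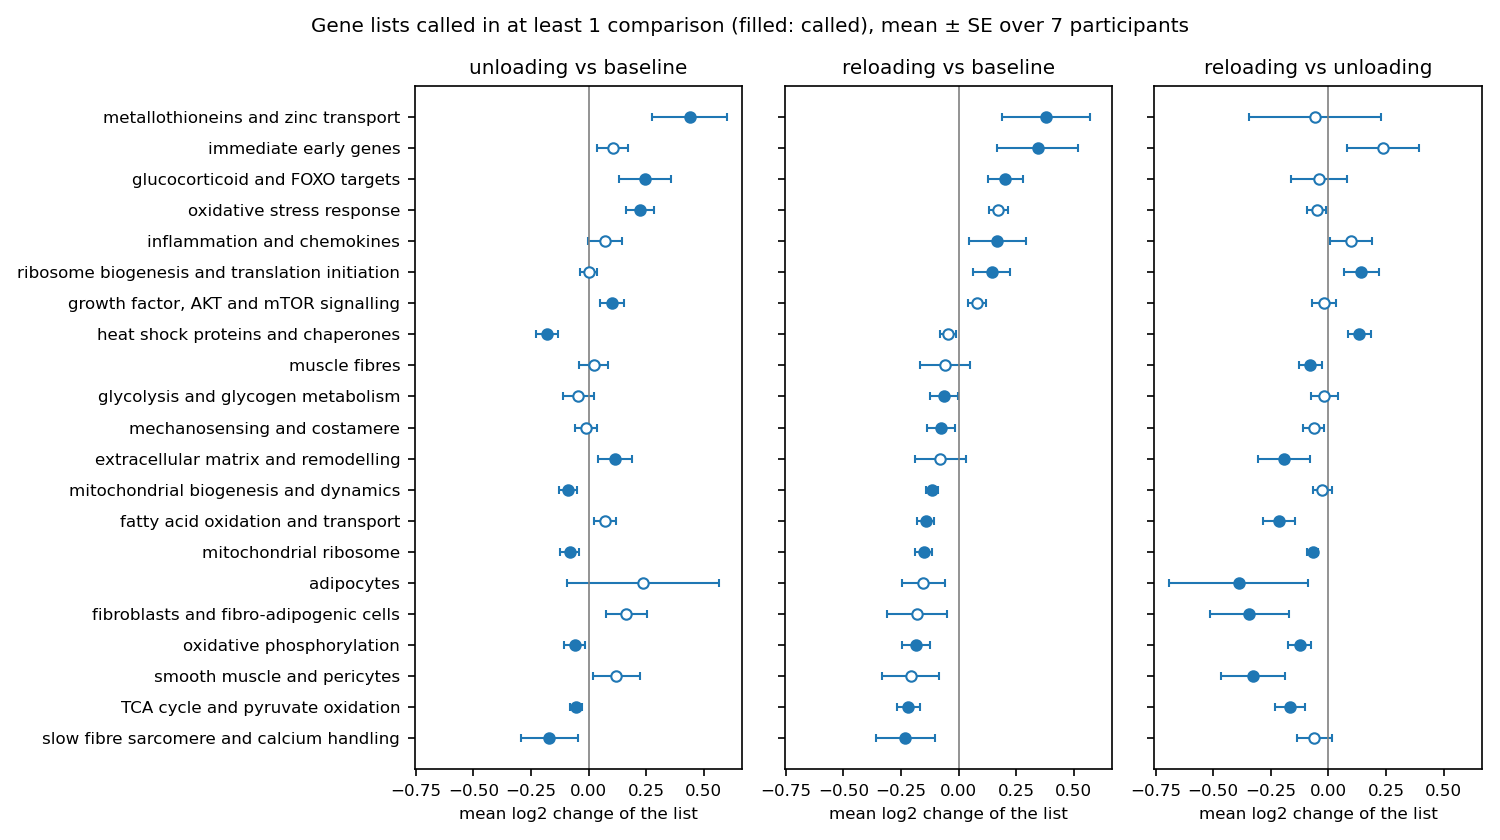
Mean log2 change of each gene list called in at least 1 comparison (horizontal axis), with the SE over the 7 participants; filled points mark lists called by camera at its preset correlation, and the panels show unloading against baseline, reloading against baseline and reloading against unloading. Oxidative phosphorylation stood at -0.06, -0.18 and -0.13 in the 3 panels, and heat shock proteins and chaperones at -0.18, -0.04 and 0.13.

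Reloading against unloading asks what changed within the 24 h of renewed weight bearing. DYNLL1, the dynein light chain that fell with unloading, rose 1.87-fold, by 0.91 ± 0.11 log2 (adjusted p = 7.83e-04), in 7 of 7 participants. STAT3 rose by 0.59 ± 0.10 log2 (adjusted p = 0.0357). DYSF, the membrane repair protein dysferlin, rose by 0.67 ± 0.12 log2 and PPP1R27, a phosphatase subunit that binds dysferlin, by 0.62 ± 0.11. The chaperone genes CHORDC1, which works with HSP90, and DNAJA1, which works with HSP70, rose by 0.67 ± 0.12 and 0.60 ± 0.11. ATOSA fell by -0.76 ± 0.14 log2, and these 5 genes had adjusted p = 0.0428.

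These 7 genes, 6 higher and 1 lower, moved the same way in 7 of 7 participants, except DNAJA1 in 6. Other probe sets gave 0.37 for DNAJA1, -0.56 for CHORDC1, -0.15 for ATOSA and 0.08 to 0.65 for STAT3. That of CHORDC1 was dim, with a mean log2 intensity of 6.04, below the filter's 7.66. At an unadjusted p under 0.05, 1239 genes passed. Without the participant block 0 genes were called (619 at an unadjusted p under 0.05, limma). Leaving out any 1 participant left 1 to 3 genes (1 without participant 4, 6 or 7, 2 without participant 1 or 2, 3 without participant 3 or 5), and leaving out the unloading array of replicate 4 left 1. With median centring 1 gene rose and 0 fell. DYNLL1 passed at 20 of 22 alternative settings. Of genes called after unloading and outside the rule here, named after their values were seen, HMOX1 stood at -1.35 ± 0.57 log2 (adjusted p = 0.431), TFRC at 0.82 ± 0.24 (adjusted p = 0.278) and EGR1 at -0.35 ± 0.35 (adjusted p = 0.777).

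Of the 44 lists, 11 were called, 2 higher and 9 lower, against 0 with an estimated correlation and 1 with fry, which was fatty acid oxidation (adjusted p = 0.0462). Other splits of the same 14 arrays gave at least 11 lists in 33 of 100, the real one included.

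Heat shock proteins and chaperones rose by 0.13 ± 0.05 log2 (adjusted p = 2.26e-04, and adjusted p = 0.315 with an estimated correlation) in 6 of 7 participants. Of 33 members, 2 rose over all genes tested (CHORDC1 and DNAJA1) and 7 adjusted over the list alone, with HSPH1 at 0.53 ± 0.11 and DNAJB4 at 0.51 ± 0.10. The call was lost without probe sets ending in _s_at or _x_at (adjusted p = 0.0926). Ribosome biogenesis rose by 0.14 ± 0.08 (adjusted p = 0.00243, and adjusted p = 0.478 with an estimated correlation) in 6 of 7 participants, with 0 of 35 members passing over all genes or adjusted over the list alone. MYC, a transcription factor that drives ribosome production, stood at 0.95 ± 0.33, DDX21 at 0.40 and GAR1 at 0.29. Without participant 6 the ribosome biogenesis list had adjusted p = 0.201.

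Lists of oxidative metabolism and of the mitochondrial ribosome fell within the reloading day, while mitochondrial biogenesis and glycolysis were not called (adjusted p = 0.269 and 0.218). Oxidative phosphorylation fell by -0.13 ± 0.05 log2 (adjusted p = 3.96e-13, and adjusted p = 0.459 with an estimated correlation) in 6 of 7 participants, with 69 of 70 members lower and 0 passing over all genes or adjusted over the list alone. SDHA stood at -0.30 ± 0.10, NDUFS6 at -0.25 ± 0.07 and ATP5MG at -0.25 ± 0.07. Fatty acid oxidation fell by -0.22 ± 0.07 (adjusted p = 3.16e-08, and adjusted p = 0.315 with an estimated correlation) in 6 of 7, with 0 of 26 members passing over all genes and 9 adjusted over the list alone, and had stood at 0.07 ± 0.05 after unloading (adjusted p = 0.416). ETFB stood at -0.41 ± 0.09 (adjusted p = 0.145) and HADHA, of the trifunctional protein, at -0.35 ± 0.09 (adjusted p = 0.244). The TCA list fell by -0.17 ± 0.07 (adjusted p = 5.95e-06, and adjusted p = 0.415 with an estimated correlation) in 5 of 7, with 0 of 22 members passing either way and the pyruvate dehydrogenase subunit PDHA1 at -0.24 ± 0.08. The mitochondrial ribosome fell by -0.07 ± 0.02 (adjusted p = 0.00761, and adjusted p = 0.521 with an estimated correlation) in 6 of 7, with 0 of 38 members passing over all genes and 1 adjusted over the list alone, MRPL16 at -0.28 ± 0.07, but its mean was 0.01 without probe sets ending in _s_at or _x_at (adjusted p = 0.617). Its call was lost with quantile normalization (0.171) and the mean of probe sets (0.0949) as well.

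Lists of markers of tissue between the fibres were also called lower within the reloading day, while exact permutation tests of the fibroblast, smooth muscle and adipocyte means over the 7 participants gave p = 0.109, 0.0781 and 0.188. The smooth muscle list also holds DES, which is in the fibre marker list as well. Fibroblast markers fell by -0.34 ± 0.17 log2 (adjusted p = 1.90e-05, and adjusted p = 0.315 with an estimated correlation) in 5 of 7 participants, with 0 of 14 members passing over all genes and 1 adjusted over the list alone. GSN, gelsolin, stood at -0.40 ± 0.11 (0.74 without probe sets ending in _s_at or _x_at), the proteoglycan DCN at -0.34 ± 0.13 and DPT, dermatopontin, at -0.83 ± 0.31. Smooth muscle and pericyte markers fell by -0.33 ± 0.14 (adjusted p = 0.00101, and adjusted p = 0.315 with an estimated correlation) in 6 of 7, with 0 of 12 members passing either way, LMOD1 at -0.64 ± 0.20 and TAGLN at -0.71 ± 0.24. Without probe sets ending in _s_at or _x_at the smooth muscle mean was 0.01 (adjusted p = 0.998), TAGLN stood at 0.03, and the fibroblast list had adjusted p = 0.0926. Adipocyte markers fell by -0.39 ± 0.30 (adjusted p = 2.69e-04, and adjusted p = 0.394 with an estimated correlation) in 5 of 7, with 0 of 10 members passing over all genes and 4 adjusted over the list alone, PLIN4, a lipid droplet protein, at -0.42 ± 0.14. The adipocyte mean on the unloading array of replicate 4 was 13.04, against 10.82 on the next, and without that array the list's change was -0.09 (adjusted p = 0.154). Without participant 4 it was -0.10 (adjusted p = 0.0992).

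Genes of the extracellular matrix fell by -0.19 ± 0.11 log2 (adjusted p = 2.36e-04, and adjusted p = 0.459 with an estimated correlation) in 6 of 7 participants. Fibroblast markers were lower too, but both lists hold genes such as DCN, LUM and COL1A1, so these are not separate results. None of the 54 matrix genes passed over all genes and 1 fell adjusted over the list alone, TIMP3, an inhibitor of matrix proteases (-0.55 ± 0.11, adjusted p = 0.103). SPARC stood at -0.41 ± 0.12 and NID1 at -0.54 ± 0.16, and against the list MMP9 at 0.54 ± 0.18. Markers of muscle fibres fell by -0.08 ± 0.05 (adjusted p = 0.0363, and adjusted p = 0.711 with an estimated correlation) in 6 of 7 participants, with 0 of 16 members passing either way, TNNT3, fast troponin T, at -0.14 ± 0.08. The fibre marker call was lost in 11 of 24 settings. These were without participant 3, 6 or 7 (adjusted p = 0.166, 0.132 and 0.146), without the unloading array of replicate 4 (0.0530), without probe sets ending in _s_at or _x_at (0.391). The others were quantile normalization (0.638), a filter at the 75th percentile (0.1), array weights (0.0563), the mean of probe sets (0.113), an estimated correlation and fry.

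**Figure D3:**
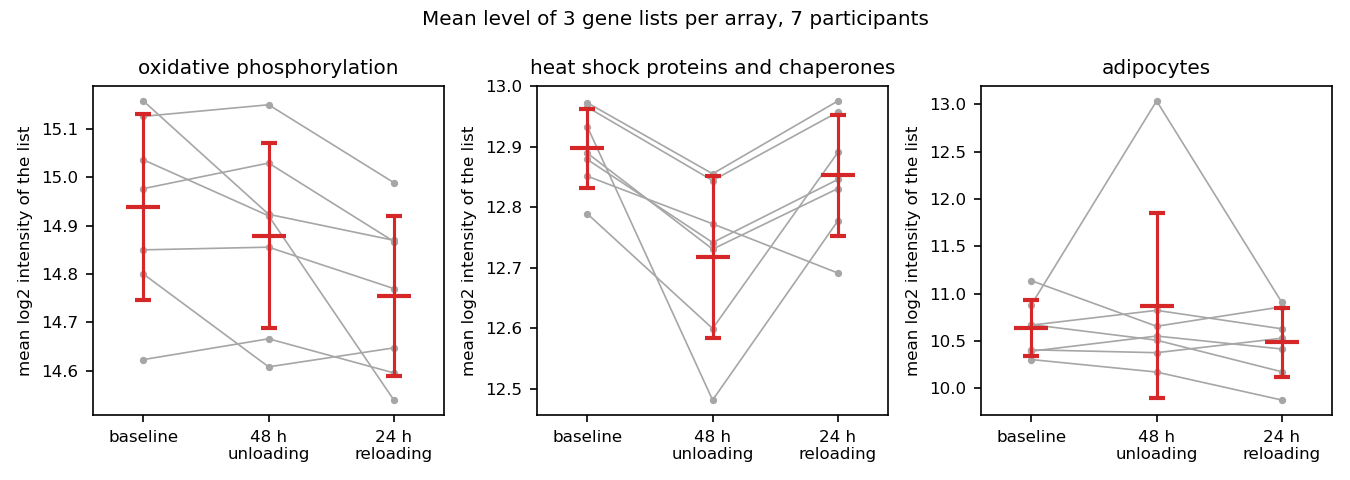
Mean log2 intensity (vertical axis) of the oxidative phosphorylation, heat shock and adipocyte lists at the 3 times; grey lines join the arrays of each of the 7 participants, and red marks give the mean ± SD. The adipocyte mean of 1 unloading array reaches 13.04, while the group means are 10.64 at baseline and 10.49 after reloading.

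Of the 21 genes called after unloading and the 3 called after reloading, both against baseline, 2 were shared, SSH2 higher and TP53INP2 lower each time. These comparisons use the same baseline arrays, and unchanged groups simulated against them shared 0 calls in each of 100 simulations, while independent lists of these sizes would share 0.00228 rises and 0.000571 falls. Across the 12258 genes, which are not independent replicates, the changes correlated with r = 0.532, against 0.499 (0.470 to 0.520) simulated for unchanged groups. In these simulations no gene was changed and noise was independent between genes, so almost no shared calls follow by construction. Genes on real arrays vary together, so the simulated range can be too narrow and does not decide whether 0.532 lies beyond chance. The covariance was 0.0365 against a simulated 0.0231, a difference of 0.0135. With the participants split into disjoint parts, so that no baseline array served both sides, the mean correlation over 70 pairs was 0.0758 (-0.0110 to 0.137) and the mean covariance 0.00922. Unloading against baseline and reloading against unloading shared 2 genes in opposite directions, ATOSA and DYNLL1, where independent lists would share 0.00457 in opposite directions and simulation gave 0.01 on average and at most 1. Their correlation was -0.464, against -0.500 simulated, the covariance was -0.0304 against -0.0232, and disjoint parts gave a mean correlation of -0.0387 (-0.118 to 0.0188). Without the participant block 0 genes were shared by the comparisons with baseline.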

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

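Chosen only after the results were seen were the tests of fibre and slow fibre content, of scaling for part of the mitochondrial fall, of 1 baseline array, of macrophages, blood and the earlier biopsy, and the within-participant exchanges for the oxidative phosphorylation and heat shock lists, while the other tests of scaling and those of cross-hybridising probe sets and of other splits were set before.

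Of 411 groups of 7 arrays examined, 19 held an array far from the others, judged by its gap to the nearest array over the group's whole range. Chance flags about 1 in 20 groups, which here would be 20.55. At baseline the gap was 0.791 for SSH2, 0.640 for TIMM8A, 0.601 for MYOM2, 0.633 for DDX21 and 0.705 for ADM, each with 1 low array, and 0.580 for MRPS12 with 1 high array. After unloading it was 0.625 for SSH2, 0.600 for GCLM and 0.791 for GYS1 with 1 low array, and 0.681 for INSR with 1 high array. Among list means after unloading it was 0.772 for adipocytes and 0.581 for glucocorticoid and FOXO targets with 1 high array, and 0.761 for mechanosensing with 1 low array. After reloading it was 0.673 for DNAJB4, 0.721 for DPT and 0.597 for COLQ with 1 low array, and 0.646 for INSR, 0.588 for OSMR and 0.570 for EDNRB with 1 high array.

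In each comparison under 0.05 of the splits called as many genes, with no allowance for the number of comparisons. Only unloading against baseline called more than every other split tried, which argues against chance for its count. For both reloading comparisons chance is not excluded, since other splits equalled or exceeded their counts. Most splits of the 14 arrays into 7 and 7 broke pairs while the participant block stayed in the fit, which can lower their counts. Of 100 splits of the 14 arrays into 7 and 7, 1 gave as many genes as the 21 of unloading against baseline (highest other 2), 2 gave as many as the 3 of reloading against baseline (highest other 53), and 1 gave as many as the 7 of reloading against unloading (highest other 2). The split that called 53 genes exchanged 1 array of each group with the other, so 6 of 7 arrays kept their time. Only 5 of 7 participants then had an array in each group. Why it called more genes was not tested, and the count of 3 is not a firm one. Of the 64 splits that part the arrays of every participant, which unlike the others keep the pairs whole, 1 gave as many as 21 (highest other 8), 2 gave as many as 3 (highest other 3) and 2 gave as many as 7 (highest other 11). The exchanges that called 3 and 11 genes were of 1 participant each.

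For the numbers of gene lists called, chance cannot be excluded in any comparison. Unloading against baseline called 11, and 22 of 100 splits did as well (highest other 18), or 10 of the 64 that part every pair (highest other 15). Reloading against baseline called 13, and 23 of 100 splits did (highest other 19), or 6 of 64 (highest other 17). Reloading against unloading called 11, and 33 of 100 splits did (highest other 16), or 20 of 64 (highest other 16).

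Oxidative phosphorylation transcripts were lower after reloading than at baseline, by -0.185 log2 on average. The tables argue against the scaling of bright probe sets as the whole cause, since 0 of 10000 random lists matched on expression had a mean as low (95% of them lay between -0.112 and -0.0454). For part of the fall scaling cannot be told apart, since the matched lists lay below 0 too, with a median of -0.0793, and a fall of bright genes can be scaling or their own change. The list's own mean was the furthest from 0 of 64 exchanges within participants, which does not allow for its choice as the list with the smallest p of 44. With that choice chance cannot be excluded. In 6 of the 64, the real one included, the smallest camera p of any list was as small (-log10 p 24.6, highest other 33.4). A lower share of muscle fibres in the biopsies cannot be told apart: the list's change less that of fibre markers was -0.128 (SD 0.173, n = 7, lower in 5 of 7, exact permutation p = 0.109). Nor can fewer slow fibres: slow less fast fibre genes changed by -0.220 (SD 0.339, lower in 6 of 7, exact permutation p = 0.141), and 7 participants are too few to settle either. A response of the fibres to unloading and reloading stays open as well, and the design cannot separate it from time and earlier biopsies.

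Heat shock transcripts were lower after unloading, by -0.179 log2, and higher again after reloading, by 0.135 over unloading. Both values use the same 7 unloading arrays, so low values on those arrays alone would give both. The tests that follow are of the fall. For the rise, an exchange of 1 participant's arrays gave a larger list mean, 0.158. Its call was lost without probe sets ending in _s_at and _x_at (camera, adjusted p = 0.0926). Cross-hybridisation is argued against for the unloading change, since without probe sets ending in _s_at and _x_at the mean of the remaining 20 genes was -0.175 (SD 0.144, n = 7, lower in 6 of 7, exact permutation p = 0.0312), and so is scaling, since 0 of 10000 matched lists had a mean as low (95% between -0.0608 and 0.0548). The baseline array of replicate 5 is argued against as well, since the mean over the other 6 participants was -0.186 (SD 0.136). The list's own mean was the furthest from 0 of 64 exchanges within participants (exact p = 0.0156), which does not allow for its choice as the list with the smallest p of 44. With that choice chance cannot be excluded, since in 32 of the 64, the real one included, the smallest camera p of any list was as small (-log10 p 6.54, highest other 21.5). Camera at its preset correlation favours lists whose genes vary together, such as cytosolic ribosomal proteins (estimated correlation 0.652, against 0.0666 for heat shock genes), so this count is a cautious one. A response to the load on the muscle, time and the earlier biopsy stay open and were not tested.

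HMOX1 was higher and TFRC lower after unloading. The lower 95% bound of the HMOX1 change was 2.45. More macrophages cannot be told apart as its source: their 15 markers changed by 0.0328 log2 on average (SD 0.428, n = 7, higher in 3 of 7), but their baseline level of 8.41 is within 1 log2 of the array median and so near the floor. Nor does HBB, the beta globin transcript, decide about blood left in the biopsy. It changed by 0.0663 log2 (SE 0.118), but its baseline level of 16.34 is close to the 16.87 of the brightest gene. A rise by the lower bound of HMOX1 could therefore not show. Other markers of red blood cells were not used for this question. An effect of the earlier biopsy cannot be told apart either, because no repeat biopsy without suspension was analysed here; the HMOX1 value of reloading against unloading, -1.35 (SE 0.57), was below 0 although that biopsy had 2 before it. A response of heme and iron handling to unloading was not tested, and biopsies repeated at the same times without suspension would separate it from the earlier biopsy.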

How the results depend on the processing

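Leaving out 1 baseline array (replicate 5) or 1 unloading array (replicate 4) was chosen after seeing the data, while the other settings were planned. The 22 settings for genes and 24 for lists gave the named genes 2609 values with the same direction and side of the threshold, 323 no longer past it, 28 newly past it and 3 reversed. Called lists kept direction and call in 701 values and lost the call in 137. HMOX1, TFRC and DYNLL1 after unloading kept their calls in 18 of 22 settings each, COL4A3 in 19, and DYNLL1 at reloading against unloading in 20. Reversed without probe sets ending in _s_at or _x_at were MRPS16 (-0.12 after unloading) and, at reloading against unloading, GSN (0.74) and TAGLN (0.027), since other probe sets then stand for these genes.

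For the counts below the cause was not tested, except that fewer arrays or another number of genes tested enters by construction. Without the replicate block no comparison called genes, that is 0 for unloading against baseline (21 with the block), 0 for reloading against baseline (3) and 0 for reloading against unloading (7), with 587, 764 and 619 at an unadjusted p under 0.05 by limma, and 0 calls were shared (2). Leaving out the block ended the calls of the TCA and matrix lists after unloading (adjusted p = 0.132 and 0.0798) and of no other list. With the block as a random effect, whose correlation was 0.288, 8 genes were called after unloading and 1 at reloading against unloading. With only the 14 arrays compared the counts were 10, 10 and 3. Without a trend in eBayes they were 0, 0 and 1 (1104, 1395 and 1160 at an unadjusted p under 0.05). The mean of probe sets gave 5 after unloading and 7 at reloading against baseline. No filter on dim probe sets gave 0 at reloading against baseline (1916 at an unadjusted p under 0.05), 2 at reloading against unloading and 0 shared calls. Reloading against baseline had 26 genes with a filter at the 75th percentile, 6 with quantile normalization, 5 with log2 of the value plus 32 and 8 without probe sets ending in _s_at or _x_at. Median centring left 1 gene at reloading against unloading. Camera with an estimated correlation called 0 lists in each comparison (0, 0 and 0), where fry called 1, 2 and 1.

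Leaving out 1 participant or 1 of those arrays gave 1 to 25 genes after unloading, 0 to 28 at reloading against baseline, 1 to 7 at reloading against unloading and 0 to 3 shared calls. List counts ran from 7 (participant 4) to 15, from 12 to 16, and from 11 to 17 (participant 2). The intensities come without detection calls, so signal over background is known only through the intensity filter, and the settings without it tested 19775 genes.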

Other observations

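The list tests in this part were planned and its genes follow the rule for lists that were not called, while the shares left at reloading were computed after the calls were seen. Lists of genes that break down muscle protein were not called after 48 h of unloading, although fry's test for members that move either way passed for atrophy ubiquitin ligases (adjusted p = 0.00337) and for autophagy and lysosome genes (adjusted p = 0.0127). The results of that either-way test for other lists are not given here, so it does not set these lists apart. Atrophy ubiquitin ligases had a mean change of 0.05 ± 0.03 log2 (SE, n = 7, adjusted p = 0.0632), with 0 of 31 members passing over all genes and 1 adjusted over the list alone, NEDD4, a ubiquitin ligase (0.38 ± 0.08 log2, adjusted p = 0.0555 over all genes, higher in 7 of 7 participants). UBE2G1, a ubiquitin-conjugating enzyme, stood at 0.26 ± 0.08 (adjusted p = 0.251). Proteasome subunits had a mean change of 0.04 ± 0.03 (adjusted p = 0.180) and autophagy and lysosome genes 0.06 ± 0.04 (adjusted p = 0.136), with 0 members passing in either list and ULK1, the kinase that starts autophagy, at 0.57 ± 0.17 (adjusted p = 0.223). After reloading the ligase list stood at 0.03 ± 0.03 over baseline (adjusted p = 0.465), with 5 members higher and 1 lower adjusted over the list alone.

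Endothelin and hypoxia genes gave single members with small p, while their list was not called. EDNRB, an endothelin receptor, stood at 1.15 ± 0.28 log2 after unloading (adjusted p = 0.112) and 0.94 ± 0.28 after reloading (adjusted p = 0.156), higher in 7 of 7 participants each time, and ADM, adrenomedullin, at 0.98 ± 0.27 after unloading (adjusted p = 0.199). The angiogenesis and hypoxia list had a mean of 0.12 ± 0.05 and a median of -0.01 after unloading (adjusted p = 0.370), so the signs differ. After reloading NOS1, the neuronal nitric oxide synthase of muscle, stood at -0.67 ± 0.16 (adjusted p = 0.0994, lower in 7 of 7) and VWF, an endothelial marker, at -0.41 ± 0.11 (adjusted p = 0.114, lower in 7 of 7), while the endothelial marker list stood at -0.04 ± 0.11 (adjusted p = 0.642). RORA, a nuclear receptor of the clock, stood at 0.53 ± 0.12 after unloading (adjusted p = 0.0908) and 0.41 ± 0.12 after reloading (adjusted p = 0.156), and the clock list at 0.04 ± 0.02 and 0.05 ± 0.08 (adjusted p = 0.447 and 0.340).

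Genes of denervation and the neuromuscular junction had a mean of -0.02 ± 0.08 and a median of 0.05 after unloading (adjusted p = 0.583) and a mean of 0.12 ± 0.08 after reloading (adjusted p = 0.136), where 4 members were higher and 1 lower adjusted over the list alone. CHRNA1, a subunit of the acetylcholine receptor, stood at 0.54 ± 0.17 after unloading (adjusted p = 0.285) and 0.68 ± 0.17 after reloading (adjusted p = 0.110). MYF6, a myogenic transcription factor, stood at 0.44 ± 0.11 after reloading (adjusted p = 0.110), and COLQ, which anchors acetylcholinesterase, at -1.37 ± 0.44 after unloading (adjusted p = 0.285). The cyclin gene CCNG2 stood at 0.75 ± 0.19 after unloading (adjusted p = 0.145) and at -0.75 ± 0.19 at reloading against unloading (adjusted p = 0.236). At reloading against unloading the growth arrest gene GADD45B stood at 0.79 ± 0.23 (adjusted p = 0.278) and KLHL40, which stabilises thin filament proteins, at 0.62 ± 0.19 (adjusted p = 0.281), each higher in 7 of 7 participants.

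Of the 21 genes called after unloading, 19 had the same sign against baseline after reloading and 20 a smaller change, the exception being TP53INP2. Genes picked for the size of 1 change tend to show smaller ones later, and reloading shares the baseline arrays, so this count is no test of recovery. As a share of the unloading change, the values ran from -35.6% for DYNLL1, past its baseline, to 122.6% for TP53INP2; ATOSA had -3.5%, and 89.5% was left for OIP5, 88.6% for SSH2, 82.5% for EGR1, 62.8% for HMOX1, 45.8% for TFRC, 15.4% for CXCL14 and 13.5% for DNAJB4.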
